A study of Homo sapiens with 12 samples.

How the data were processed

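Poly(A) RNA of the human colon cancer cell line HCT116 was sequenced on an Illumina HiSeq instrument, per the labels and the series design text. There were 12 libraries in 4 groups of 3. The groups were p53+/+ cells with a scrambled control, p53+/+ cells depleted of Mina53, p53-/- cells with the scrambled control, and p53-/- cells depleted of Mina53. Mina53 is the protein of the gene RIOX2, whose older symbol is MINA. Groups and replicate numbers were taken from the sample titles. The type of depletion reagent, the time of harvest, and whether the replicates were separate cultures are not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical.

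The authors deposited a table of 36615 gene symbols by 12 libraries, and its header names no unit. The values were read as FPKM (fragments scaled to transcript length and library size) because the deposited columns are not whole numbers, sum to between 348822 and 372821 per library, and are corrected for length. The neighbouring mitochondrial genes ND4L and ND4, of very different length on a shared transcript, had a ratio of values between 0.970 and 1.06. Reads were filtered and matched to the human genome by the authors, and the build is hg19 per the submitters' processing notes. The aligner, the quantification tool and the gene annotation are not given in the sources used here. The low values show no whole-read steps, so the depth of each library is unknown and no counting interval can be given. Column names with the prefix KO were read as p53-/- cells and columns without it as p53+/+ cells. No coordinates are given, since the table holds none and the reference used here is of another build.

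Because the values are not counts, they were tested on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean. Fold changes are on that scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 3 libraries were kept, which left 13728. A single fit with 1 mean per group used all 12 libraries and left 8 residual degrees of freedom. From it came 4 comparisons, namely depletion against scrambled control in each genotype, the difference of those effects (p53-/- minus p53+/+), and p53-/- against p53+/+ scrambled controls. P-values were adjusted with the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. On simulated data with 50 genes for each fold size, a log2 change of 0.5 was recovered for 92% of genes in p53+/+ depletion, 90% in p53-/- depletion, 70% in the difference of the effects and 92% between the controls. For a log2 change of 0.25 the shares were 36%, 34%, 14% and 42% in the same order. These simulations ran on 13728 genes and gave between 4 and 8 false calls. They changed far fewer genes than passed in the data, where 32.9% to 63.4% of genes were called. The adjusted threshold is looser when more genes change. Neither the shares recovered nor the number of false calls therefore carries over to the data.

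Before the data were examined, 32 gene lists with 909 entries were written. They cover p53 targets, G2/M and mitosis, G1/S and replication, DNA repair, apoptosis, MYC targets, ribosome biogenesis, ribosomal proteins, nuclear and mitochondrial genes of oxidative phosphorylation, interferon response, NF-κB, the unfolded protein and integrated stress responses, heat shock, cholesterol synthesis, hypoxia and glycolysis, NRF2, WNT, TGF-β and matrix, epithelial adhesion, colon differentiation, immediate early and MAPK genes, histones, JmjC oxygenases with arginine methyltransferases, autophagy and lysosome, and senescence. The other lists hold markers of fibroblasts, immune, erythroid, neuronal and endothelial cells, and of kidney and liver lines. Of the entries, 838 matched a symbol of the table directly, 40 through an older symbol, 8 repeated a member and 23 had no match. Of the table's symbols, 34011 are in the RefSeq gene table used for names. Lists were tested with the camera function of limma at a preset correlation of 0.01, adjusted over 124 tests of 31 lists in 4 comparisons. The endothelial list had 1 member past the filter and was not tested. Of the 124 tests, 58 passed the threshold. With a correlation estimated from the data 7 passed. Those were p53 targets in p53+/+ depletion, in the difference of the effects and between the controls, interferon response in p53-/- depletion, in the difference and between the controls, and G2/M in the difference. Counts of members adjusted over the list alone equalled the counts over all genes in 94 of the 124 tests and differed by at most 4 in the others.

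Genes were named by a rule fixed before the data were examined. It takes RIOX2; for each comparison the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the highest group and, between 2 groups, no overlap of libraries; the 4 members with the smallest p of each list described; the p53 targets CDKN1A, MDM2, BAX, BBC3, PMAIP1 and GDF15; and MYC, RIOX1, PRMT1 and RPL27A as genes tied to Mina53. Clone names, pseudogenes, microRNA and transfer RNA genes, read-through genes and copies that share reads were passed over. Some genes that the rule picks are not reported here.

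Replicates correlated at r = 0.992 to 0.995 within groups and at 0.928 to 0.969 between groups, across genes, which are not independent. No pair of libraries held identical values. The alternatives were a TMM-type rescaling that trims 30% of log ratios and 5% of levels at each end, limma without the trend, no filter, a filter at 5 FPKM, a pseudocount of 0.1, only the groups compared, the replicate number as a block, each library left out, and an absolute log2 fold change of at least 1. Alternatives added after the data were seen left out mitochondrial genes with rescaling, or kept only genes without certain sequence words in their 3' UTR. The 3' UTR is the part of a transcript after the coding sequence. Its longest version per gene was taken from the protein-coding transcripts of GENCODE and searched for words of 7 bases, with length and GC content of the 3' UTR in the model. Of the 13728 genes, 11359 (82.7%) had such a sequence of at least 50 bases, and 16205 of the 16384 words were in at least 50 genes and were ranked. On simulated data a word whose genes were lowered by 0.1 ranked first in 10 of 10 sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.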

Results

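HCT116 is a human colon cancer line that exists as a p53+/+ line and as a p53-/- line made from it. RNA levels were measured in both lines after depletion of Mina53, a nucleolar oxygenase of the JmjC family, and in scrambled controls. Each of the 4 groups had 3 libraries. Values are given as mean FPKM ± SD with n = 3 libraries per group, and library totals ranged from 348822 to 372821 FPKM. The first 2 principal components held 49.4% and 33.7% of the variance.

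The depleted gene was checked first. RIOX2 fell from 7.49 ± 0.252 to 2.72 ± 0.291 FPKM in p53+/+ cells, which leaves 36.3% of the control level (log2 fold change -1.19, SE 0.070, adjusted p = 3.53e-08). In p53-/- cells it fell from 9.09 ± 0.211 to 2.02 ± 0.242 FPKM, or 22.3% of control (log2 fold change -1.74, adjusted p = 2.03e-09). The fall was deeper in p53-/- cells by a log2 difference of -0.55 (SE 0.099, adjusted p = 0.00142).

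**Figure D1:**
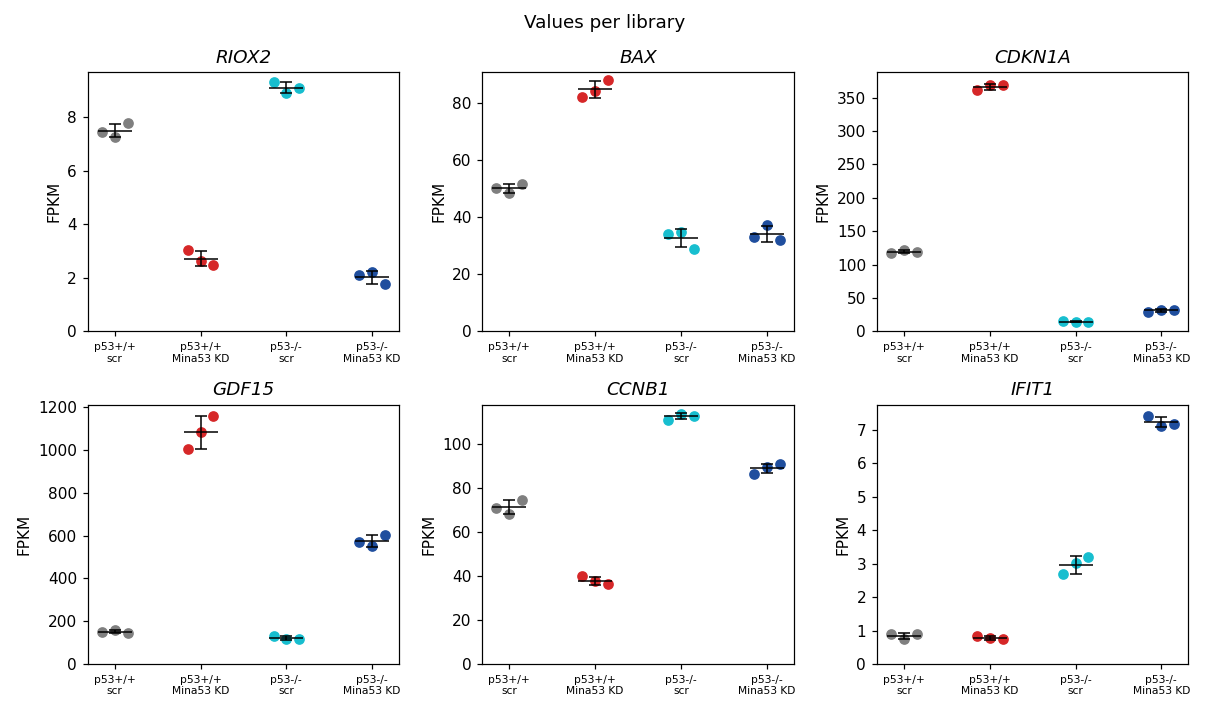
FPKM of 6 genes in each of the 12 libraries (points), with the group mean (horizontal bar) and SD (error bar, n = 3), by genotype and treatment. RIOX2 is lower in every depleted library than in the controls of its genotype, while CDKN1A rises from 119.5 to 366.7 FPKM in p53+/+ cells and from 14.3 to 31.2 in p53-/- cells.

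The comparison of depleted with control p53+/+ cells asked what loss of Mina53 changes in cells that carry p53. Targets of p53 rose and cell cycle genes fell. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 119.5 ± 1.97 to 366.7 ± 4.32 FPKM (log2 fold change 1.61, adjusted p = 7.89e-11). GDF15, a secreted stress cytokine, rose from 150.8 ± 7.15 to 1082 ± 77.2 FPKM, and 34 of 47 measured p53 targets rose against 2 that fell. All 35 genes of the G2/M and mitosis list and 39 of 40 genes of the G1/S and replication list fell.

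The p53 target list had a median log2 fold change of 0.56 (camera adjusted p = 3.13e-09, and 0.00221 with an estimated correlation), and 34 rises and 2 falls also held when adjusted over the list alone. Besides GDF15 and CDKN1A, its members with the smallest p were BTG2 (1.40) and SESN2 (1.74), an antiproliferative gene and a stress-induced sestrin. BAX, which permeabilises mitochondria, rose from 50.1 ± 1.62 to 84.8 ± 3.005 FPKM, BBC3 (PUMA) rose from 10.8 ± 0.730 to 23.9 ± 2.21, and PMAIP1 (NOXA) rose from 13.9 ± 0.730 to 19.0 ± 2.02. MDM2, the ubiquitin ligase that degrades p53, was at 14.3 ± 0.908 and 12.9 ± 1.38 FPKM and did not pass the threshold (adjusted p = 0.144). Without depleted p53+/+ replicate 1 its log2 fold change was -0.21 (adjusted p = 0.0210).

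The G2/M list had a median of -1.0004 (camera adjusted p = 2.98e-18; adjusted p = 0.0745 with an estimated correlation), with 35 falls also when adjusted over the list alone. MKI67, the proliferation marker, fell by 1.35 on the log2 scale, CDC20 by 1.18, TPX2 by 1.17 and BIRC5 by 1.13. The G1/S list had a median of -0.80 (adjusted p = 1.61e-16; adjusted p = 0.0745 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 58.8 ± 3.15 to 11.7 ± 0.409 FPKM, and the replicative helicase genes MCM2, MCM4 and MCM7 fell by 1.34, 1.27 and 1.11. Of 30 DNA repair genes 25 fell, and 26 when adjusted over the list alone (median -0.64, adjusted p = 1.05e-08; adjusted p = 0.137 with an estimated correlation), among them FANCD2 (-1.03), BRCA1 (-1.02), FANCA (-0.87) and FANCI (-0.86).

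Other large rises were PRF1, which encodes perforin, from 4.20 ± 0.193 to 53.5 ± 1.60 FPKM, the membrane protein gene SUSD2 from 1.14 ± 0.0984 to 9.33 ± 0.227, and the small GTPase gene RHOB from 44.6 ± 2.73 to 207.6 ± 14.1. The water and glycerol channel AQP3, APOE, the proapoptotic BIK, HES2 and the cytokine subunit EBI3 rose by log2 fold changes between 1.83 and 1.88. GDF15 overlaps the microRNA gene MIR3189, and their reads cannot be separated here. The largest falls after RRM2 were CYB5R3 (cytochrome b5 reductase) from 38.1 ± 1.32 to 8.27 ± 0.759 FPKM, PTMA (prothymosin alpha) from 1401 ± 49.4 to 351.0 ± 14.3, and ANXA2 (annexin A2) from 679.1 ± 10.1 to 206.2 ± 1.9992. PTMA and ANXA2 have pseudogene copies that fell with them and may share reads, so their values are uncertain. ORC6 of the origin recognition complex, ESCO2 of sister chromatid cohesion, HR, the long noncoding RNA LNCAROD, PRR11 and FOSL1 fell by log2 fold changes between -1.64 and -1.57. Of 9 largest falls whose 3' UTR was searched, 5 hold a sequence word described under the other observations, against 36.3% of genes. RRM2, CYB5R3 and ANXA2 are among them. Those words were chosen in this comparison, and an effect of the reagent on such genes was not separated from loss of Mina53.

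The hypoxia and glycolysis list fell in 22 of 27 genes with 2 rises (median -0.71, adjusted p = 2.21e-07; adjusted p = 0.249 with an estimated correlation), with VEGFA at -1.49, HK2 at -1.46, BNIP3 at -1.34 and LDHA at -0.97. Of 77 ribosomal protein genes 66 fell (median -0.26, adjusted p = 7.70e-14; adjusted p = 0.145 with an estimated correlation). RPL7A (-1.42), RPL13A (-1.31), RPL14 (-0.76) and RPL12 (-0.69) had the smallest p, and genes of this family have many pseudogene copies that may share reads. RPL27A, whose protein is a substrate of Mina53, fell from 155.3 ± 2.57 to 128.7 ± 1.37 FPKM. MYC was at 91.4 ± 3.08 and 82.2 ± 2.39 FPKM (log2 fold change -0.15, adjusted p = 0.00531), a call that was lost when mitochondrial genes were left out (adjusted p = 0.203). The related oxygenase gene RIOX1 rose from 1.94 ± 0.0832 to 3.36 ± 0.259 FPKM, and the methyltransferase gene PRMT1 was at 166.7 ± 6.09 and 156.0 ± 6.10 (adjusted p = 0.0836). PRMT1 passed without control replicate 2 (adjusted p = 0.0447) or without depleted replicate 3 (adjusted p = 0.0410). Genes of TGF-β response and matrix rose in 16 of 20 cases with 3 falls (median 0.45, adjusted p = 5.98e-05; adjusted p = 0.0910 with an estimated correlation), with SPARC (1.19), TGFB1 (0.96) and MMP14 (0.75).

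In all, 8334 of 13728 genes passed the threshold, 3916 higher and 4418 lower, and 446 of them changed by a log2 fold change of at least 1. Mitochondrial protein-coding transcripts took 14.1% ± 0.270 of the library total in controls and 18.6% ± 0.737 after depletion. With mitochondrial genes left out and libraries rescaled, 4940 genes were higher and 3394 lower, so the balance of rises and falls depends on the scaling.

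The comparison within p53-/- cells asked the same of cells that lack p53. Interferon genes rose, replication genes fell, and 15 p53 targets rose while 15 fell. Of 27 interferon response genes 25 rose and 0 fell, also when adjusted over the list alone (median 0.90, camera adjusted p = 9.46e-12, and 0.00221 with an estimated correlation). IFI6 rose by 1.75, IRF9 by 1.32 and OAS3 by 0.90 on the log2 scale. Of 40 G1/S genes 34 fell, and 35 when adjusted over the list alone (median -0.45, adjusted p = 7.57e-10; adjusted p = 0.108 with an estimated correlation), with RRM2 from 92.6 ± 2.58 to 22.5 ± 0.978 FPKM, MCM2 at -0.99, MCM6 at -0.62 and MCM3 at -0.55.

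DNA repair genes fell in 20 of 30 cases with 3 rises (median -0.25, camera adjusted p = 0.000487, and adjusted p = 0.344 with an estimated correlation). The p53 target list did not pass (median 0.0039, adjusted p = 0.527). Within it CDKN1A rose from 14.3 ± 0.546 to 31.2 ± 1.77 FPKM, GDF15 from 121.8 ± 9.15 to 574.1 ± 27.5, PMAIP1 from 31.3 ± 2.03 to 76.7 ± 3.27 and BBC3 from 5.9967 ± 0.992 to 10.9 ± 0.926, and BTG2 rose by 1.15. MDM2 fell from 8.32 ± 0.715 to 6.53 ± 0.253 FPKM. BAX was at 32.7 ± 3.25 and 34.0 ± 2.81 FPKM (adjusted p = 0.495). The G2/M list did not pass (median -0.09, adjusted p = 0.0553), though it did without the filter on low values (adjusted p = 0.000785) and with only the groups compared (adjusted p = 0.0459). This list also passed without p53+/+ depleted replicate 3 (adjusted p = 0.0459), p53-/- control replicate 1 (0.0294) or p53-/- depleted replicate 2 (0.0387). In it 16 of 35 genes fell and 4 rose, and CDC20 (-0.52), BIRC5 (-0.49), CCNB1 (-0.34) and MKI67 (-0.31) had the smallest p.

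Of 40 MYC target genes 28 fell and 2 rose (median -0.26, adjusted p = 1.39e-06; adjusted p = 0.0937 with an estimated correlation), with the chaperonin HSPD1 at -1.61, nucleolin (NCL) at -1.09, SLC19A1 at -0.74 and CDK4 at -0.69. In p53+/+ cells 20 of the 40 MYC targets fell and 9 rose, and the list did not pass (median -0.14, camera adjusted p = 0.0683). It did pass there without the filter on low values (adjusted p = 0.00173) and without p53+/+ control replicate 2 (0.0441). MYC itself fell from 48.3 ± 0.948 to 39.1 ± 1.70 FPKM in p53-/- cells. Ribosomal protein genes fell in 46 of 77 cases with 2 rises (median -0.12, adjusted p = 8.90e-06; adjusted p = 0.363 with an estimated correlation), with RPL7A at -1.22, RPS12 at -0.84, RPL13A at -0.61 and RPL10A at -0.45. RPL27A fell from 116.8 ± 3.02 to 104.1 ± 3.01 FPKM. RIOX1 rose from 3.96 ± 0.474 to 5.41 ± 0.516, and PRMT1 was at 185.9 ± 8.99 and 180.7 ± 6.44 (adjusted p = 0.464).

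The largest rise was again PRF1, from 1.56 ± 0.125 to 16.997 ± 0.287 FPKM. The chemokine CXCL8 rose from 0.621 ± 0.0835 to 7.54 ± 0.838, the glucose transporter SLC2A3 from 1.35 ± 0.0572 to 11.1 ± 0.628, RASD1 from 0.350 ± 0.0975 to 5.37 ± 0.953, and the phosphatase DUSP5 from 18.2 ± 0.380 to 69.5 ± 1.36. The small heat shock protein HSPB8, the interferon-induced IFI27, the matricellular CCN1 and the stress factor ATF3 rose by log2 fold changes between 1.77 and 1.96. CYB5R3 fell most, from 45.4 ± 0.200 to 5.74 ± 0.0535 FPKM. PTMA fell from 1102 ± 40.6 to 233.6 ± 4.40, ANXA2 from 693.5 ± 25.8 to 154.0 ± 8.26 and SLC9A3R2 from 11.9 ± 0.703 to 2.22 ± 0.420, and the pseudogene limit on PTMA and ANXA2 holds here too. The choline transporter SLC44A1, the purine enzyme PNP, the ATP synthase subunit gene ATP5MC2 and JTB fell by log2 fold changes between -1.90 and -1.88. Among the 10 largest falls here 8 hold a 3' UTR word described under the other observations, so the limit on the reagent applies again. Of the genes past the threshold 14 fell by more than RIOX2 did, against 101 in p53+/+ cells. These ranks are on the log2(FPKM + 1) scale, which shrinks the fall of RIOX2 more than that of abundant genes. With the pseudocount of 0.1 its log2 fold change was -2.12 in p53-/- cells and -1.43 in p53+/+ cells, and ranks were not recomputed.

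In this comparison 8071 genes passed, 3968 higher and 4103 lower, and 359 changed by a log2 fold change of at least 1. The split was 4148 higher and 3898 lower with TMM-type scaling, and 4439 and 3574 with mitochondrial genes left out, so which direction is larger depends on the scaling here too. Mitochondrial protein-coding transcripts rose from 10.5% ± 0.476 to 14.1% ± 0.284 of the library total.

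**Figure D2:**
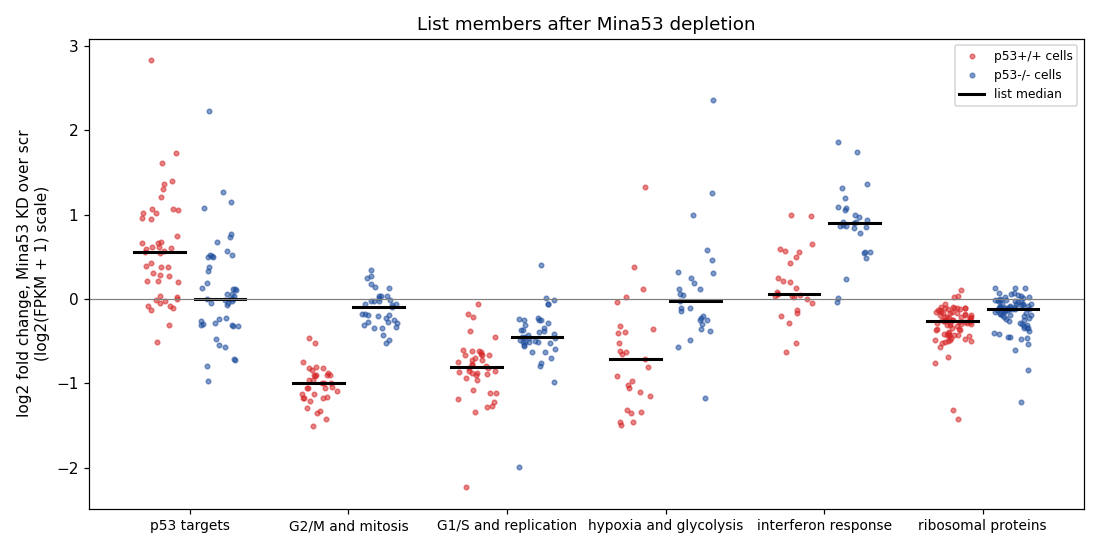
Log2 fold change (Mina53 depletion over scrambled control, log2(FPKM + 1) scale) of each measured member of 6 gene lists in p53+/+ cells (red) and p53-/- cells (blue), with the list median as a black bar. The G2/M median is -1.0004 in p53+/+ cells and -0.09 in p53-/- cells, and the interferon median is 0.06 and 0.90.

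The difference between the depletion effects was tested directly, as the effect in p53-/- cells minus that in p53+/+ cells. G2/M genes, hypoxia genes and interferon genes had higher effects in p53-/- cells, and p53 targets had lower ones. All 35 G2/M genes differed in the same direction, also when adjusted over the list alone (median difference 0.89, camera adjusted p = 1.82e-28, and 0.0409 with an estimated correlation). For NUSAP1, KIF20A, MKI67 and TPX2, which act in the spindle or mark proliferation, the difference lay between 0.89 and 1.14. Of 47 p53 targets 33 had a lower effect in p53-/- cells and 3 a higher one, and 36 and 3 when adjusted over the list alone (median -0.53, adjusted p = 1.02e-13, and 0.00221 with an estimated correlation). FDXR, a mitochondrial ferredoxin reductase, went from 39.8 ± 0.871 to 81.6 ± 2.18 FPKM in p53+/+ cells and from 18.0 ± 0.979 to 14.2 ± 0.696 in p53-/- cells. The kinase PLK2, the repair factor XPC and the nuclease AEN differed by -1.10, -0.76 and -0.79.

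Of 27 interferon genes 25 had a higher effect in p53-/- cells (median 0.78, adjusted p = 2.13e-13, and 0.00221 with an estimated correlation). In p53+/+ cells 10 of them rose and 4 fell (median 0.06, adjusted p = 0.139). Low values limit this comparison, since the log2(FPKM + 1) scale compresses their changes. IFIT1 was at 0.74 to 0.90 FPKM in the p53+/+ libraries and at 2.68 to 7.42 in the p53-/- libraries. How many other members lay as low in p53+/+ cells was not counted. Of 27 hypoxia and glycolysis genes 23 had a higher effect (median 0.77, adjusted p = 7.52e-17; adjusted p = 0.0937 with an estimated correlation). In p53-/- cells the list itself did not pass, with 9 genes higher and 10 lower (median -0.03, adjusted p = 0.798), so the difference lies mainly in the fall in p53+/+ cells. The list was already lower in p53-/- than in p53+/+ controls (median -1.41). The lack of a fall in p53-/- cells cannot be told apart from that lower baseline. BNIP3, a mitophagy receptor, fell from 77.6 ± 3.04 to 30.1 ± 1.98 FPKM in p53+/+ cells and rose from 14.7 ± 0.679 to 20.7 ± 0.551 in p53-/- cells. ANGPTL4 went from 32.4 ± 2.82 to 20.8 ± 2.07 FPKM and from 3.36 ± 0.154 to 7.73 ± 0.195, and BNIP3L and LDHA differed by 1.22 and 0.73.

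CXCL8 had the largest positive difference, 1.99. The clock factor BHLHE40, the arrestin-related ARRDC3, the AP-1 member FOSL2, keratin KRT7, the hypoxia-linked noncoding RNA MIR210HG, LY6D and the epithelial factor ELF3 followed with differences between 1.4954 and 1.69. LY6D is listed at 0 in all p53-/- libraries, so its difference is the fall from 6.60 ± 0.192 to 1.70 ± 0.389 FPKM in p53+/+ cells alone. PDE2A had the largest negative difference, -1.97, with 5.59 ± 0.205 and 20.3 ± 1.27 FPKM in p53+/+ cells and 1.07 ± 0.102 and 0.718 ± 0.158 in p53-/- cells. SUSD2, KLF2, the sestrin SESN3, APOE, ALDH1L1, RHOB, PHOSPHO1 and VPS9D1-AS1 had differences between -1.73 and -1.27, and the last is an antisense gene whose reads may not be separated from its partner's. ALDH1L1 was close to the floor of the scale in p53+/+ controls, so a fall in p53+/+ cells could hardly be measured for it. Among p53 targets fixed beforehand, CDKN1A (-0.53), BAX (-0.69) and GDF15 (-0.60) had a lower effect in p53-/- cells and PMAIP1 (0.84) a higher one. MDM2 (-0.17, adjusted p = 0.247), BBC3 (-0.30, adjusted p = 0.122), MYC (-0.15, adjusted p = 0.0627), RIOX1 (-0.20, adjusted p = 0.206), PRMT1 (0.05, adjusted p = 0.537) and RPL27A (0.10, adjusted p = 0.0873) did not pass. BBC3 passed without p53-/- control replicate 3 (adjusted p = 0.0332). MYC passed without p53+/+ control replicate 3 (adjusted p = 0.0410), p53+/+ depleted replicate 1 (0.0480) or p53-/- depleted replicate 1 (0.0398), and with mitochondrial genes left out (0.0109).

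The effects of depletion correlated across genes at r = 0.688, where genes are not independent replicates and the comparisons share no control libraries. There were 2533 genes higher in both genotypes, against 1132 if the calls were independent, and 2838 lower in both, against 1320. In opposite directions there were 509 genes, against 2447. The difference itself passed the threshold for 4511 genes, 2286 with a higher and 2225 with a lower effect in p53-/- cells, and for 155 it was at least 1 on the log2 scale. With mitochondrial genes left out the split was 1781 higher and 2806 lower. Each genotype is represented by a single line, so a difference between the lines other than p53 enters this comparison as well.

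**Figure D3:**
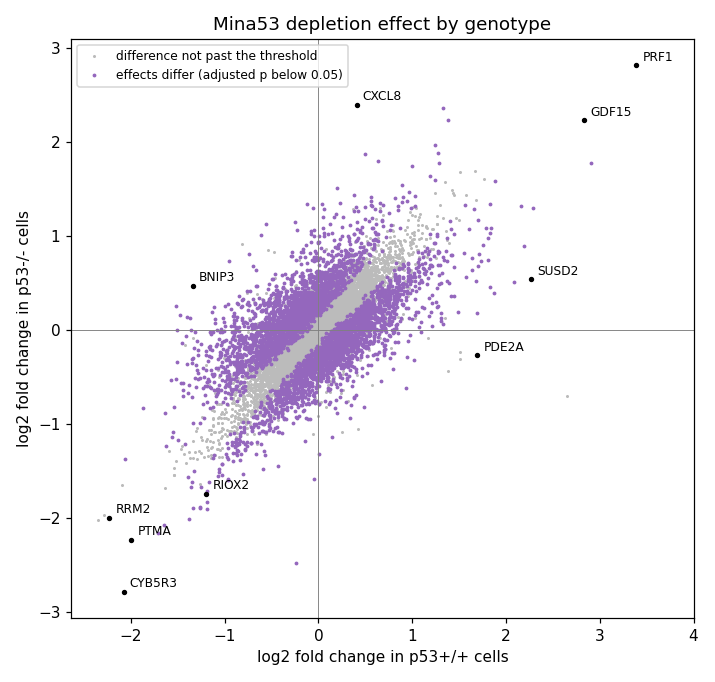
Log2 fold change on Mina53 depletion of each of 13728 genes in p53+/+ cells (x axis) and p53-/- cells (y axis), with genes whose effects differ past the threshold in purple (4511) and the others in grey. CXCL8 and BNIP3 lie above the diagonal, SUSD2 and PDE2A below it, and PRF1, GDF15, CYB5R3 and PTMA change in the same direction in both lines.

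Scrambled controls of the lines were compared to describe the baseline. Most p53 targets were lower in p53-/- cells, 37 of 47 against 6 higher (median -0.52, camera adjusted p = 2.47e-09, and 0.00221 with an estimated correlation), and adjusted over the list alone the counts were also 37 and 6. CDKN1A was at 14.3 ± 0.546 FPKM in p53-/- and 119.5 ± 1.97 in p53+/+ cells, and BTG2, DDB2 and RPS27L were lower by log2 fold changes of -2.06, -1.59 and -1.30. MDM2 (-0.71), BAX (-0.61), BBC3 (-0.77) and GDF15 (-0.31) were lower and PMAIP1 (1.12) was higher. Of 27 hypoxia and glycolysis genes 23 were lower (median -1.41, adjusted p = 9.14e-16; adjusted p = 0.0937 with an estimated correlation). The glucose transporter SLC2A1 was at 12.2 ± 0.120 FPKM against 220.6 ± 5.14, NDRG1 at 23.7 ± 1.36 against 271.9 ± 18.9, and BNIP3 (-2.32) and ANGPTL4 (-2.94) were lower as well. Of 77 ribosomal protein genes 72 were lower and 0 higher, and 73 lower when adjusted over the list alone (median -0.50, adjusted p = 6.32e-26; adjusted p = 0.0909 with an estimated correlation), with RPL12 at -1.06, RPL4 at -0.76 and RPL5 at -0.74. Interferon genes were higher in 19 of 27 cases (median 0.53, adjusted p = 0.000125, and 0.0425 with an estimated correlation), with OAS3 (1.22), IFI6 (1.20), IFIT3 (1.16) and IFIT1 (1.10) first by p.

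VIM, the intermediate filament of mesenchymal cells, was at 61.5 ± 1.52 FPKM in p53-/- controls and 1.20 ± 0.0352 in p53+/+ controls. The epithelial factor EHF was at 23.9 ± 1.15 against 0.799 ± 0.121, ALDH1L1 at 12.7 ± 0.894 against 0.0122 ± 0.0106, and the kallikrein KLK6 at 98.0 ± 2.68 against 14.6 ± 0.746. DHRS2, CCDC102B, PRPS1, CHAC1, GPR15 and KLK7 were higher by log2 fold changes between 2.40 and 2.98. ANXA10 was at 0.0409 ± 0.0355 FPKM against 25.2 ± 0.767, DPEP1 at 0.224 ± 0.0935 against 20.3 ± 0.862, and WNT16 at 2.81 ± 0.163 against 37.0 ± 0.0325. The carbonic anhydrase CA9 (-3.38) and the nuclear receptor PPARG (-3.02) were lower, and LY6D was at 6.60 ± 0.192 FPKM in p53+/+ controls and listed at 0 in p53-/- controls. MYC was at 48.3 ± 0.948 against 91.4 ± 3.08 FPKM and RPL27A at 116.8 ± 3.02 against 155.3 ± 2.57. RIOX2 (0.25) and RIOX1 (0.75) were higher. PRMT1 was higher by 0.16 (adjusted p = 0.00891) and lost the call with TMM-type scaling (adjusted p = 0.121). Between the controls 8701 genes passed, 5045 higher and 3656 lower in p53-/- cells. Of these, 556 differed by a log2 fold change of at least 1, and there 227 were higher and 329 lower. Over all genes that passed, TMM-type scaling gave 4327 higher and 4201 lower, so the excess of higher genes depends on the scaling.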

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

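The tests of explanations in this part were chosen after the results had been seen, except the counts of other splits of the libraries, which were set before they were computed. Each result here was listed because the effect of Mina53 depletion differed between the genotypes by a test of the difference itself, given as the effect in p53-/- cells minus that in p53+/+ cells on the log2 scale.

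The difference passed the threshold for 4511 genes. Of 100 drawn splits of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many. The highest other split gave 2074, so an arbitrary division of these libraries is argued against. Splits that mix the groups add the differences between groups to the spread, which lowers their counts. They say nothing of a technical difference that goes with the groups. The count of genes called in the same direction in both genotypes, 5371, was reached by 1 of the 100 splits, with 0 as the highest other value. The 58 list tests that passed were reached by 1 of 100 splits, but another split reached 57. The number of list calls therefore sets the real groups little apart from that split. Calls with an estimated correlation were not counted over splits. For the comparisons of 3 with 3 libraries, 1 of 10 splits gave as many genes each time. The counts were 8334 in p53+/+ depletion with 0 in the highest other split, 8071 in p53-/- depletion with 1, and 8701 between the controls with 1, and 10 splits are too few for a share under 0.05.

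Among gene lists, median differences were 0.89 for G2/M, 0.78 for interferon response, 0.77 for hypoxia and glycolysis, 0.45 for NF-κB, 0.42 for G1/S, 0.36 for DNA repair, 0.36 for senescence, 0.34 for cholesterol synthesis, 0.18 for histones and 0.13 for ribosomal proteins. They were -0.53 for p53 targets, -0.52 for the 3 measured neuronal markers, -0.16 for WNT targets, -0.16 for MYC targets, -0.14 for NRF2 targets and -0.11 for autophagy and lysosome. With an estimated correlation the adjusted p was 0.00221 for p53 targets and interferon and 0.0409 for G2/M, and the others ranged from 0.0745 to 0.353. Some of these lists also differed between the controls at the preset correlation. Of 40 G1/S genes 33 were higher and 2 lower in p53-/- controls (median 0.46, camera adjusted p = 1.88e-06, and 0.173 with an estimated correlation). Of 25 cholesterol synthesis genes 16 were lower and 4 higher there (median -0.42, camera adjusted p = 0.000624, and 0.127 with an estimated correlation). Several calls for the difference of the effects also ended under other settings. Among genes without the 3' UTR words the NRF2 median was -0.05 (adjusted p = 0.450), and autophagy (adjusted p = 0.157) and senescence (adjusted p = 0.0617) did not pass. With the filter at 5 FPKM autophagy (adjusted p = 0.0521), NF-κB (0.0939), senescence (0.106) and WNT targets (0.0680) did not pass, and WNT targets did not with the pseudocount of 0.1 (0.0527). NF-κB did not pass when any depleted p53-/- library was left out (adjusted p from 0.0650 to 0.0977), senescence did not in 7 of the 12 fits with a library left out, and WNT targets did not in 2.

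Genes with a higher effect in p53-/- cells were CXCL8 (1.99), BNIP3 (1.81), BHLHE40 (1.69), ARRDC3 (1.68), KRT7 (1.64), ANGPTL4 (1.62), FOSL2 (1.55), MIR210HG (1.54), LY6D (1.51), ELF3 (1.4954), BNIP3L (1.22), NUSAP1 (1.14), IFIT1 (1.11), KIF20A (1.05), MKI67 (1.04), OAS3 (1.03), DTX3L (0.98), TPX2 (0.89), PMAIP1 (0.84), USP18 (0.84) and LDHA (0.73). Those with a lower effect were PDE2A (-1.97), SUSD2 (-1.73), KLF2 (-1.55), SESN3 (-1.51), APOE (-1.48), FDXR (-1.34), ALDH1L1 (-1.33), RHOB (-1.30), PHOSPHO1 (-1.30), VPS9D1-AS1 (-1.27), PLK2 (-1.10), AEN (-0.79), XPC (-0.76), BAX (-0.69), GDF15 (-0.60), RIOX2 (-0.55) and CDKN1A (-0.53).

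G2/M genes fell in p53+/+ cells by a median of -1.0004 (camera adjusted p = 2.98e-18, and adjusted p = 0.0745 with an estimated correlation). In p53-/- cells their median was -0.09 and the list did not pass (camera adjusted p = 0.0553). The list did pass there under some other settings, among them no filter on low values (adjusted p = 0.000785) and only the groups compared (0.0459). A weaker depletion in p53-/- cells is argued against by RIOX2, which fell further there (difference -0.55). Direct silencing through the 3' UTR words chosen under the other observations is argued against by the 27 members without any of them. Their median in p53+/+ cells was -1.0001, with all 27 lower. Those members may still hold other low words, such as CATTCCA, which overlaps ACATTCC and was at rank 3 from the lowest in p53+/+ cells and rank 2 in p53-/- cells. Silencing of a gene that regulates them was not tested. With TMM-type scaling the median difference was 0.88. That scaling moved all genes in this comparison by a median of only -0.0099, so the test could hardly have come out otherwise. It shows only that the change between these scalings is too small to account for the difference. G2/M genes also differed at baseline, with 20 of 35 higher and 2 lower in p53-/- than in p53+/+ controls. Their median there was 0.23 (camera adjusted p = 0.00505, and 0.440 with an estimated correlation). Whether that baseline enters the difference of the effects was not tested. A role of p53 and of other differences between the lines stays open, since each genotype is a single line.

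Interferon genes rose in p53-/- cells by a median of 0.90. RNA from immune cells is argued against by 15 immune markers with a median of 0.12 FPKM in the depleted p53-/- libraries, where 12 were below 0.5 and PTPRC was at 0.0029; the most abundant, CD68, was at 7.11 FPKM and is made by many cell types. ITGAX is an exception that rose there from 0.255 to 1.66 FPKM. With TMM-type scaling the median difference was 0.77, with the same limit, since that scaling moved all genes by a median of only -0.0099. A response to the reagent was not tested apart from the depletion and may remain, as may an effect of p53 or of the line, which already had higher interferon genes in its p53-/- controls.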

How the results depend on the processing

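The alternatives without mitochondrial genes and without genes holding the 3' UTR words were chosen after seeing the data. The named genes followed under the alternatives were the largest rises and falls and the genes fixed beforehand. Genes named only as list members were not followed. None of the genes followed and no list turned in direction under any alternative where either fit called it. Each library left out in turn gave 7618 to 8350 genes in p53+/+ depletion, 7277 to 8077 in p53-/- depletion, 3805 to 4428 for the difference of the effects, 7909 to 8701 between the controls, 5004 to 5208 called in the same direction in both genotypes, and 53 to 61 list tests. RIOX2 ranged from -1.26 to -1.15 in p53+/+ cells and from -1.79 to -1.67 in p53-/- cells. Requiring an absolute log2 fold change of at least 1 left 446, 359, 155 and 556 genes, fewer by construction, in the order p53+/+ depletion, p53-/- depletion, difference and controls. Genes without the 3' UTR words gave 4655, 4468, 2593 and 4799 and 3016 called alike in both genotypes, also fewer because fewer genes enter; RIOX2 itself is not among them. An estimated correlation left 7 of the 58 list tests. The filter at 5 FPKM and the absence of a filter gave 6189 and 8755 genes in p53+/+ depletion. The largest move of the median of all genes under another scaling was 0.08.

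The replicate number as a block gave 8123, 7818, 4139 and 8520 genes and 57 list tests. It ended 1 list call and changed no call of the named genes that were followed. Same-numbered libraries did not deviate together: over 18 pairs the correlation of their deviations ran from -0.23 to 0.16, and 3 of 12 libraries were closest to their own number. The unknown depth limits what can be said of genes with low values.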

Other observations

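The explanation tests in this part were chosen after both depletion comparisons had been seen, and so was the search of the 3' UTR.

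Some further lists passed after depletion at the preset correlation, and none of those in this and the next paragraph passed with an estimated correlation. Transcripts of the mitochondrial genome were higher in 10 of 13 genes in p53+/+ cells (median 0.39, camera adjusted p = 4.29e-05; adjusted p = 0.280 with an estimated correlation) and in 13 of 13 in p53-/- cells (median 0.42, adjusted p = 4.10e-06; adjusted p = 0.241 with an estimated correlation), with CYTB at 0.83 and 0.71. Nuclear genes of oxidative phosphorylation did not pass (medians -0.06 and 0.03). Immediate early and MAPK genes rose in 16 of 25 cases with 4 falls in p53+/+ cells (median 0.34, adjusted p = 0.00271, and 0.137 with an estimated correlation). In p53-/- cells 17 of 25 rose and 4 fell (median 0.40, adjusted p = 6.47e-05, and 0.0910 with an estimated correlation). DUSP5 was among the rises (1.28 and 1.88), while FOSL1 of the same list was among the largest falls in p53+/+ cells. Cholesterol synthesis genes rose in 17 of 25 cases with 3 falls in p53-/- cells (median 0.24, adjusted p = 0.000163, and 0.0937 with an estimated correlation), led by INSIG1 (1.34). In p53+/+ cells that list did not pass (median -0.0043). TGF-β and matrix genes rose in p53-/- cells too (15 of 20 with 3 falls, median 0.46, adjusted p = 0.000234, and 0.0937 with an estimated correlation). That call ended among genes without the 3' UTR words (median 0.34, adjusted p = 0.0549). Core apoptosis genes rose in 14 of 25 cases in p53+/+ cells (median 0.24, adjusted p = 0.0131) and 15 of 25 in p53-/- cells (median 0.21, adjusted p = 0.00214), with adjusted p = 0.137 and 0.0937 with an estimated correlation.

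Further lists with a call in a single depletion comparison were autophagy and lysosome in p53+/+ cells (median 0.13, adjusted p = 0.00956; 0.285 as adjusted p with an estimated correlation), WNT targets in p53+/+ cells (0.26, adjusted p = 0.0346; 0.131 as adjusted p with an estimated correlation), and in p53-/- cells ribosome biogenesis (-0.10, adjusted p = 0.00956; 0.520), NF-κB (0.35, adjusted p = 0.0306; 0.131) and senescence (0.42, adjusted p = 0.00290; 0.0745), the last value of each being the adjusted p with an estimated correlation. A call in a single genotype is not by itself a difference between the genotypes. In p53-/- cells the medians were 0.11 for autophagy and 0.14 for WNT targets. In p53+/+ cells they were -0.09 for ribosome biogenesis, -0.11 for NF-κB and 0.28 for senescence. The difference of the effects did not pass for ribosome biogenesis (camera adjusted p = 0.0675), though it did without the filter on low values (0.00342). The senescence call in p53-/- cells ended among genes without the 3' UTR words (median 0.13, adjusted p = 0.0656). The WNT call ended with the filter at 5 FPKM (adjusted p = 0.153) and with mitochondrial genes left out (0.0506). The NF-κB call ended with that filter (adjusted p = 0.255), with the pseudocount of 0.1 (0.0544), and when any depleted p53-/- library was left out (0.210 to 0.282). No depletion comparison passed for the unfolded protein and stress response list (medians -0.14 and -0.22), heat shock (0.07 and -0.03), NRF2 (0.06 and 0.02), epithelial adhesion (-0.08 and -0.02), colon differentiation (-0.02 and 0.08), histones (0.20 and 0.21), or JmjC oxygenases with arginine methyltransferases (-0.03 and 0.03), p53+/+ first. Without the filter on low values the stress response list passed in p53-/- cells (median -0.17, adjusted p = 0.00173) and ribosome biogenesis in p53+/+ cells (adjusted p = 0.0150). No marker list of another cell type passed, with medians of 0.37 and 0.25 for fibroblasts, -0.07 and -0.16 for immune cells, -0.47 and -0.24 for erythroid cells, 0.36 and 0.11 for neurons, and -0.06 and -0.14 for kidney and liver lines. The neuronal markers passed in p53+/+ cells without control replicate 2 (median 0.42, adjusted p = 0.0498). Between the controls, epithelial adhesion genes were lower in p53-/- cells in 19 of 25 cases (median -0.33, adjusted p = 5.09e-06; adjusted p = 0.0745 with an estimated correlation), with CDH1 at -1.05, and stress response genes were higher in 18 of 28 (median 0.49, adjusted p = 0.000286; adjusted p = 0.137 with an estimated correlation), with PHGDH at 1.4975. Between the controls the 3 measured neuronal markers were higher in p53-/- cells (median 0.63, adjusted p = 0.0375; adjusted p = 0.145 with an estimated correlation, and 0.430 without the filter on low values). The 4 measured erythroid markers were lower (median -0.64, adjusted p = 0.0375; adjusted p = 0.160 with an estimated correlation, and 0.0554 with TMM-type scaling).

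Genes that hold certain words of 7 bases in the 3' UTR were lower after depletion in both lines. Of 16205 words, ACATTCC was lowest in p53+/+ cells (z = -7.99 over 1506 genes, mean difference -0.09 log2) and, in the separate p53-/- libraries, lowest again (z = -11.44, difference -0.13). ACCTGGC and GACAGAG, the other words chosen in p53+/+ cells, had z = -7.81 and -7.63 there and -8.21 and -9.53 in p53-/- cells. A hypothesis is that the depletion reagent may also silence transcripts through short seed matches, as small interfering RNAs can. It is in line with the z of -11.44, since shuffled values gave no z below -4.64 and the words had z of -1.09, -0.77 and 1.22 between the controls. Base composition of the 3' UTR is argued against by other words of the same bases that do not overlap, whose lowest z in p53-/- cells was -2.53 for ACATTCC, -3.83 for ACCTGGC and -2.90 for GACAGAG. Words that overlap the chosen ones were also among the lowest. They were CATTCCA and CCTGGCA in p53+/+ cells (z = -7.71 and -6.35) and CATTCCA and ACAGAGA in p53-/- cells (z = -10.87 and -8.77). The evidence has gaps. ACATTCC is in 1 of 9 annotated RIOX2 transcripts and absent from the longest, while ACCTGGC and GACAGAG are in 4 and 5 of them, and the reagent's sequence is not given in the sources used here. The reverse complements of the words were not searched for in RIOX2, and which of its transcripts these cells express was not tested. The fall did not grow steadily with the number of distinct words, with medians in p53-/- cells of 0.03, -0.06, -0.07 and -0.07 for 0, 1, 2 and 3 words. Unlike the z values, these medians and the counts of largest falls below are not adjusted for 3' UTR length or GC content. A trend with the number of words is therefore not settled by them. Of the 10 largest falls in p53-/- cells 8 hold at least 1 of the words, among them CYB5R3, ANXA2 and RRM2, and so do 5 of the 9 searched in p53+/+ cells, against 4120 of all 11359 genes searched (36.3%). The words were chosen for low values in p53+/+ cells, so part of that excess follows from the choice. PTMA holds none of them. Regulation by cellular microRNAs after loss of Mina53 was not tested and stays open, since depletion and reagent always go together here.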
